A study of Mus musculus with 8 samples.

How the data were processed

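Small RNA libraries of myoblasts from 4 old and 4 young C57BL/6J mice were compared, with RNA isolated by a mirVana kit and sequenced on an Illumina GAIIx per the labels. The labels number the mice within each group, and these numbers name the libraries here (old 1 to old 4, young 1 to young 4). The submitters' processing notes name BWA and the build mm10, with no version or role; the counting rule, adapter trimming, filters and the treatment of reads that match several precursors are not given in the sources used here. The authors deposited log2 values with 2 decimals for 1181 miRNA precursors in 8 columns, floored at 0, so that a linear value under 1 is listed as 0; 400 precursors are at 0 in all libraries. The arms of a precursor are not separated.

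The scale of the deposited log2 values was tested on the values themselves. Among the lowest values, up to 12 reads, the linear value times precursor length fell on a whole multiple of a step in 99.5% to 100% of cases (111 to 216 values per library, tolerance 0.1 of a read). With lengths shuffled 50 times it did so in 20.0% to 20.9%, and in 22.4% to 31.1% if the values were log2 of the linear value plus 1. This is how RPKM values (reads per kilobase of precursor, scaled to library size) behave, and the library sizes given in the report (25.1 to 39.4 M reads) rest on that reading. Reads recovered in this way are not whole at high values because of the rounding of the logs, and were used for an alternative only. Reads are not independent molecules, and counting error is small beside the spread between libraries for abundant miRNAs.

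The planned test was limma on log2 of the value plus 1, written for linear values. Since the file holds log2 values, limma 3.58.1 (R 4.3.3; eBayes with a mean-variance trend) was run on them as deposited, with no pseudocount and no rescaling, and differences are old minus young on that scale; the floor at 0 understates differences of low miRNAs. Precursors with a linear value of at least 10 in at least 4 libraries were kept, 359 in all. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. With 4 against 4 libraries, two-sided exact permutation tests over 70 arrangements can give no p below 0.0286. Lists of miRNAs (23, for muscle, imprinted, proliferation, inflammation, Hox and other families and for markers of other cell types) were fixed before the data were examined, and the 18 with at least 3 kept members were tested with limma's camera (preset correlation 0.01, and again with an estimated correlation) and fry. Principal components and Spearman correlations were computed on the kept precursors. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

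miRNAs were named by a rule fixed before the data were examined: miR-431, up to 12 rises and 12 falls past the threshold (there were none), the 10 smallest p if fewer than 10 passed, up to 4 of the most abundant members of each list, and the 5 most abundant miRNAs. miR-10a and miR-10b in the closing section were singled out after their values were seen. Positions are from a RefSeq table of the GRCm38 assembly, the same build as mm10, with overlapping genes from a GENCODE annotation; 1175 of 1181 precursors, and 359 of 359 kept ones, were matched by identifier or name.

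The tests were checked on simulated data with known changes for 359 miRNAs (20 sets, 60 changed in each): 15% of 2-fold, 59.2% of 4-fold and 80% of 8-fold changes were recovered, 3.99% of calls were false, and a list shifted by 1.5 was found in 20 of 20 sets. No other list was called in them. In the real libraries, by contrast, camera called 1 to 8 lists in each of the 35 splits into 4 and 4. The simulated sets therefore cannot show the false calls or the power of the list tests in these data. Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, no filter or a mean of at least 100, median-ratio, TMM and quantile rescaling, limma without trend or with array weights, the replicate number as a block, and leaving out each library. A pseudocount of 1, a rescaling to the sum without mir-486 and mir-3107, voom on recovered reads, averaging of precursor copies and leaving out both old 3 and young 4 were added after seeing the data. Count-model tests were not run, since the file holds log2 values. No library was left out of the main comparison and the deposited labels were kept throughout.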

Results

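Small RNA was sequenced from myoblasts, the muscle precursor cells that proliferate and fuse into fibres, of 4 old and 4 young mice, with 1 library per animal as the labels number them. The question the series title raises is how miRNAs, and miR-431 in particular, differ between old and young muscle cells. Each library gave a log2 abundance for 1181 miRNA precursors, of which 588 to 635 per library were above 0. The 359 precursors with a linear value of at least 10 in at least 4 of the 8 libraries were compared. If the values are RPKM (reads scaled by precursor length and library size), as their steps behave, the libraries held 25.1 to 39.4 M reads, with a mean of 26.3 ± 1.2 M in old and 33.6 ± 4.07 M in young libraries (SD, n = 4 each). Every young library was then larger than every old one (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The reads recovered per precursor summed to 28.1 ± 4.38 M in old and 37.0 ± 6.32 M in young libraries (n = 4 each, exact permutation p = 0.0857), and old 1 at 33.0 M lay above young 2 at 30.8 M and young 4 at 32.8 M. This sum exceeded the library size in 5 of 8 libraries, since it counts reads listed under more than 1 precursor again. Without mir-3107, which repeats the reads of mir-486, it was 18.5 ± 2.38 M and 25.2 ± 2.08 M (n = 4 each, exact permutation p = 0.0286) and exceeded the library size in 0 libraries.

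The mir-486 locus and the mir-99b, mir-151 and mir-92a-1 precursors had the highest means over the 8 libraries. mir-486, a muscle-enriched miRNA in an intron of Ank1 on chromosome 8 (23142555 to 23142682, plus strand, mm10), had a log2 abundance of 21.41 ± 0.28 in old and 21.28 ± 0.81 in young libraries (SD, n = 4 each). mir-3107, which lies inside it on the minus strand (23142573 to 23142662), was the most abundant precursor, at 21.93 ± 0.28 and 21.80 ± 0.81. The values of these precursors differed by 0.51 to 0.52 in every library, against 0.51 for the log2 ratio of their lengths, so the same reads were in effect listed under both names and their separate levels cannot be read from this file. mir-3107 alone held 35.8 ± 3.81% of the summed linear values in old and 32.4 ± 10.8% in young libraries (n = 4 each, two-sided exact permutation p = 0.600), from 19.1% in young 4 to 42.8% in young 1. The 10 most abundant precursors together held 85.0 ± 2.53% and 83.4 ± 6.76% (exact permutation p = 0.686). Without young 4 the differences turned to -1.01 and -1.15 percentage points, from 3.41 and 1.64 with all libraries. mir-99b, in an intron of Spaca6 on chromosome 17, measured 19.16 ± 0.60 in old and 18.91 ± 0.61 in young libraries. mir-151, in an intron of Ptk2 on chromosome 15, measured 18.88 ± 0.29 and 19.09 ± 0.73. mir-92a-1, in an exon of the Mir17hg transcript on chromosome 14, measured 18.66 ± 0.37 and 18.92 ± 0.55. None of these 5 differed between the groups by more than the spread between libraries (limma, adjusted p = 0.995 for each).

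The libraries did not sort by age. Over the 359 miRNAs the mean Spearman correlation was 0.921 between libraries of the same group and 0.924 between libraries of different groups, with pairs from 0.863 to 0.977. The closest library to old 3 was young 3, with a correlation of 0.977, and the closest to young 4 was old 4, with 0.958. The first principal component held 49.1% of the variance, and 66.1% of its squared loadings belonged to the 37 miRNAs of the Dlk1-Dio3 cluster. It placed old 1, old 2, old 4 and young 4 on its negative side and old 3, young 1, young 2 and young 3 on its positive side. With the cluster left out, the first component held 37.6% of the variance and set young 4 and old 4 apart from the other 6 libraries.

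**Figure D1:**
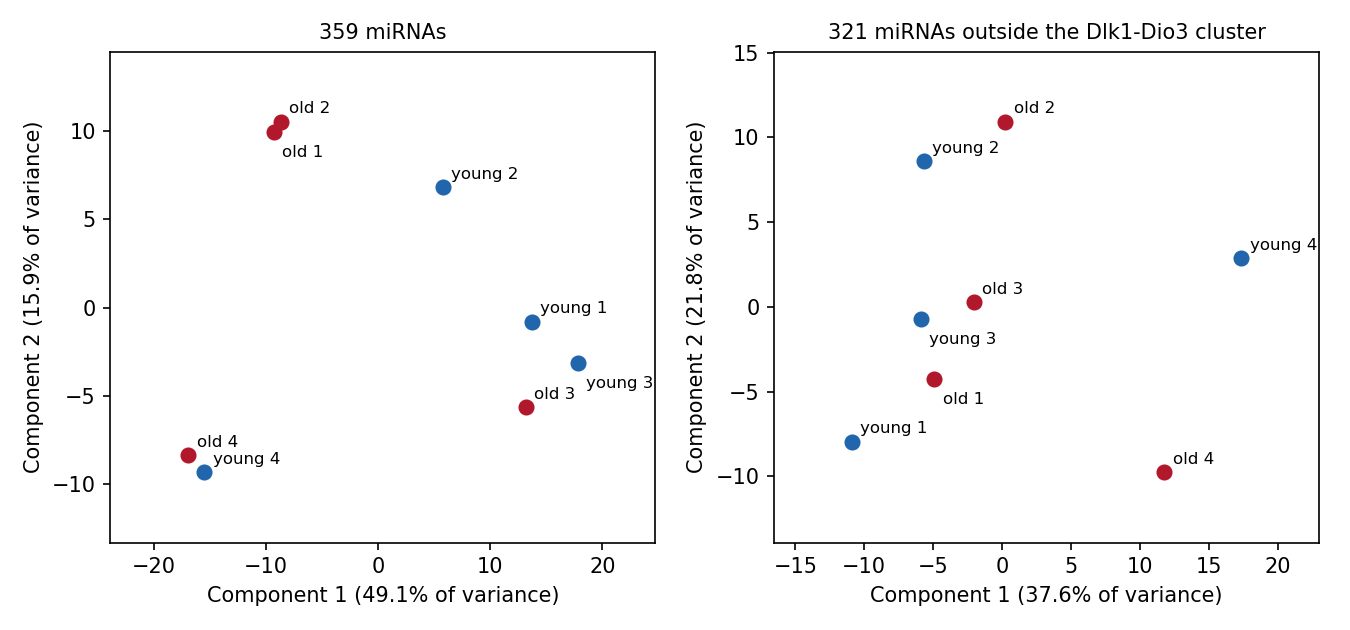
Principal components of log2 abundance over the 359 miRNAs (left) and over the 321 miRNAs outside the span from mir-673 to mir-410 of the Dlk1-Dio3 cluster (right). The 321 include mir-1247, which lies beyond this span in an exon of Dio3os. Axes are in arbitrary units, with 1 point per library (old in red, young in blue). On the left the first component, with 49.1% of the variance, puts old 3 beside young 1 and young 3, and young 4 beside old 4.

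miR-431, the miRNA named in the series title, was lower on average in old myoblasts, but the difference did not pass the test. Its precursor lies on chromosome 12 (109590447 to 109590537, plus strand, mm10), antisense to an exon of Rtl1 and within the imprinted Dlk1-Dio3 region. Its log2 abundance was 7.12 ± 2.02 in old and 8.93 ± 1.93 in young libraries (SD, n = 4 each), a mean log2 difference of -1.81 with an SE of 1.15 and a 95% interval from -4.39 to 0.78. Young libraries thus held 3.50 times as much on the geometric mean (limma, p = 0.149, adjusted p = 0.995, two-sided exact permutation p = 0.314). The old libraries were at 6.17, 6.39, 10.14 and 5.80, and the young ones at 9.09, 9.23, 11.05 and 6.36, so that old 3 lay among the young libraries and young 4 among the old ones. The lowest library still held 127.2 recovered reads of miR-431. Without old 3 the difference was -2.81 (adjusted p = 0.261), without young 4 it was -2.67 (adjusted p = 0.568), and without young 3 it was -1.10 (adjusted p = 0.993). Without both old 3 and young 4 it was -3.67 with an adjusted p of 0.00720. Those libraries were picked because of their values at this locus, so that p is not evidence of a difference with age.

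The other miRNAs of the Dlk1-Dio3 cluster, a maternally expressed group on chromosome 12, took the same course as miR-431. The 37 compared precursors on its list span 109571990 to 109743795 (mm10), from mir-673 to mir-410, with 6 overlapping Rtl1, 2 Rian and 9 Mirg. They are not 37 separate measurements: mir-299a and mir-299b overlap and differed by -0.37 to -0.36 in every library, and mir-3071 and mir-136 by -0.38 to -0.36 in the 7 libraries where both were above 0, as the ratios of their lengths give (-0.36 and -0.37), so that the same reads were in effect listed under both names and 35 were without repeats. A 38th compared precursor of this span, mir-3544, was not on the list; it lies inside mir-337, differed from it by -0.68 in every library (length ratio -0.67), and measured 5.88 ± 1.79 in old and 7.23 ± 1.62 in young libraries (SD, n = 4 each). All 37 had a lower mean in old than in young libraries, with log2 differences from -2.58 to -1.10 and a median of -1.61, and 0 passed the threshold singly, either over all miRNAs or adjusted over the list alone. With the replicate number as a block, 28 passed in limma adjusted over the list alone and 0 over all miRNAs. The labels give no pairing by number, so the unblocked count was kept as the result. mir-127, the most abundant member, measured 15.94 ± 1.85 in old and 17.55 ± 1.72 in young libraries. mir-541 measured 11.94 ± 1.97 and 13.82 ± 1.65, mir-673 10.34 ± 1.83 and 12.07 ± 1.77, and mir-411 9.50 ± 1.95 and 10.98 ± 1.47 (SD, n = 4 each). The mean over the 37 was 4.86, 5.39, 8.99 and 4.80 in old 1 to old 4 and 8.38, 7.34, 9.56 and 5.53 in young 1 to young 4. Old 3 therefore stood 3.97 above the mean of the other old libraries, and young 4 stood at -2.90 relative to the other young libraries. A two-sided exact permutation test of the list means gave p = 0.229 (6.01 ± 2.0 against 7.70 ± 1.71, n = 4 each). The list was lower in old libraries by limma's camera with its preset correlation of 0.01 (adjusted p = 4.04e-22, 18 lists), but not with an estimated correlation (adjusted p = 0.630, the members' correlation being 0.897) nor by fry (adjusted p = 0.992). Without old 3 the median was -2.59 and 32 of the 37 passed when adjusted over the list alone, while the median was -2.44 without young 4 and -1.01 without young 3, with 0 passing in either case. Without both old 3 and young 4, 33 of the 359 miRNAs passed in limma, 31 of them on this list, against 0 with all libraries; the libraries were chosen on the outcome.

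**Figure D2:**
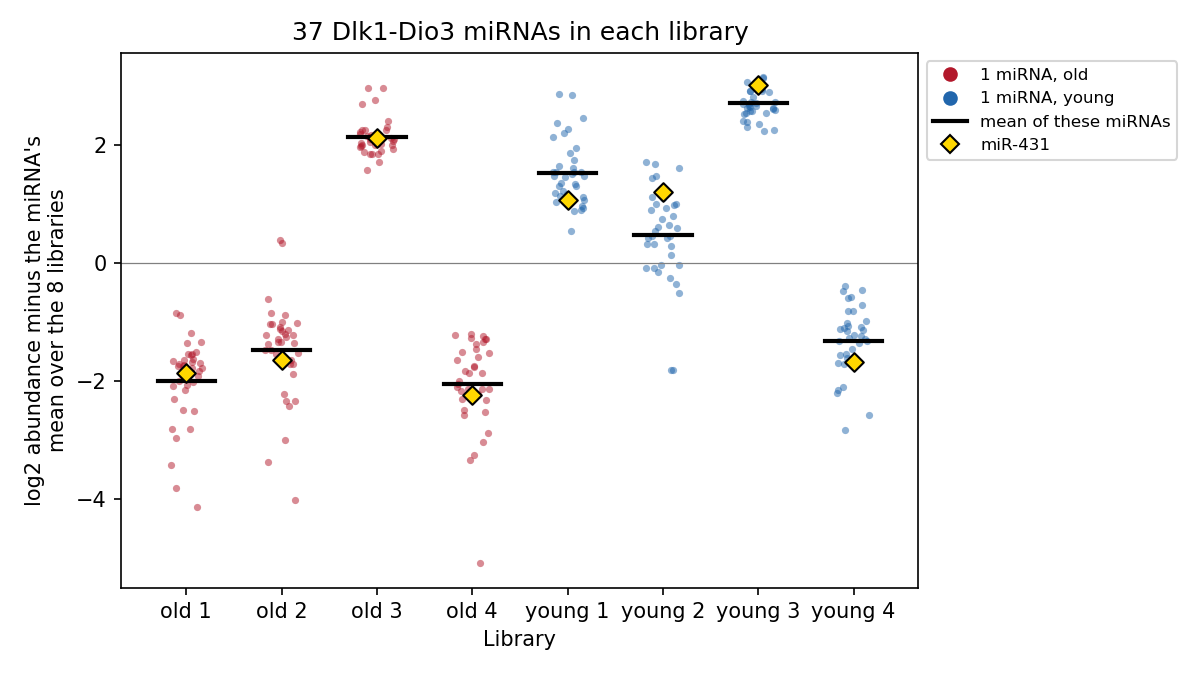
Log2 abundance of the 37 Dlk1-Dio3 miRNAs in each library minus each miRNA's mean over the 8 libraries, with 1 point per miRNA, a black bar for their mean and a diamond for miR-431. The miRNAs of old 1, old 2, old 4 and young 4 lie mostly below 0 and those of old 3, young 1, young 2 and young 3 mostly above it.

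Across all 359 miRNAs, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.995. At an unadjusted p under 0.05 there were 4, where 17.95 would arise by chance, 2 higher and 2 lower in old libraries. This count was 36 without old 3, 27 without young 4, 1 without old 2 and 2 without old 4 or without young 3. Groups that did not overlap were seen for 3 miRNAs (0.836%, against 2.86% by chance). The median difference was -0.05, and the median SD within a group was 0.67. Voom on recovered reads also gave 0, with 1 at an unadjusted p under 0.05. On simulated changes in 60 of 359 miRNAs the same test recovered 15% of 2-fold, 59.2% of 4-fold and 80% of 8-fold changes. In such sets 2-fold changes were mostly missed. These shares are taken over all simulated miRNAs and do not give the power for those that vary most. The SE of miR-431 was 1.15, against a median of 0.50 over the 359 miRNAs, so larger changes could be missed there too.

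The 10 miRNAs with the smallest p did not pass the threshold (adjusted p = 0.995 for each in limma). mir-146a, a miRNA induced by NF-kB signalling, on chromosome 11 (43374397 to 43374461, mm10), measured 5.48 ± 0.97 in old and 4.10 ± 0.28 in young libraries, a difference of 1.38 with an SE of 0.54 (limma p = 0.0300, two-sided exact permutation p = 0.0286). All 4 old libraries lay above all 4 young ones. mir-147, also an inflammation-linked miRNA, in an exon of AA467197 on chromosome 2, measured 5.84 ± 1.09 and 4.22 ± 1.63. mir-193b, on chromosome 16, measured 8.82 ± 0.29 and 7.78 ± 0.98. mir-5131, in an exon of Ddhd1, and mir-7003, in an intron of Mybl2, were at 4.04 ± 0.51 and 4.01 ± 0.54 in old and at 2.48 ± 1.15 and 2.36 ± 1.63 in young libraries. Lower means in old libraries were found for mir-6997, in an intron of Sptan1 (2.45 ± 0.92 against 3.86 ± 0.41), for mir-8111 (3.02 ± 0.98 against 4.36 ± 0.54) and for mir-6901, in an exon of Sned1 (2.49 ± 0.94 against 3.77 ± 1.07). The other 2 were the Dlk1-Dio3 members mir-380 (2.06 ± 2.54 against 4.62 ± 1.78) and mir-668 (6.67 ± 1.75 against 8.56 ± 1.64; SD, n = 4 each throughout). Single libraries moved several of these differences by over 1.5 times: without young 1 that of mir-147 went from 1.62 to 0.95, that of mir-7003 from 1.65 to 0.87 and that of mir-5131 from 1.55 to 1.0, without young 2 that of mir-193b went from 1.04 to 0.59, and without old 4 that of mir-8111 went from -1.34 to -0.89.

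Beside the Dlk1-Dio3 cluster, 3 other lists passed camera with the preset correlation, all with higher values in old libraries. With an estimated correlation the adjusted p was 0.630 for each of these 3 lists, and with fry 0.992. The estimated correlation of the members was 0.802 for Sfmbt2, 0.404 for fibroblast and smooth muscle and 0.337 for inflammation, against the preset 0.01. Two-sided exact permutation tests of the list means gave p = 0.229, 0.286 and 0.171 in the same order. Of the 81 listed repeated miRNAs of the Sfmbt2 intron 6 were compared, mir-467d and 5 precursors of the mir-669 group. They were higher for 6 of 6 members with a median of 0.68 (adjusted p = 0.000689). Among them were mir-669c at 6.98 ± 0.83 against 6.39 ± 0.70 and mir-467d at 5.96 ± 0.59 against 5.59 ± 0.56. The other members were less abundant, such as mir-669o at 3.81 ± 0.85 against 3.135 ± 1.08 and mir-669a-5 at 3.445 ± 0.60 against 2.49 ± 1.16. Of these, mir-669a-5, mir-669a-7 and mir-669a-9 are numbered copies of mir-669a, so the 6 members are not all separate miRNAs. The fibroblast and smooth muscle markers were higher for 6 of 6 members with a median of 0.29 (adjusted p = 0.0155). Of these members, the copies mir-199a-1 and mir-199a-2 ran parallel over the libraries (11.32 and 10.73 in old 1, 12.12 and 11.54 in young 4). They do not count as separate measurements. mir-143, abundant in smooth muscle and fibroblasts, measured 15.20 ± 0.31 in old and 14.79 ± 0.54 in young libraries, mir-214 measured 12.71 ± 0.54 and 12.26 ± 0.58, and mir-199a-1 measured 11.70 ± 0.50 and 11.41 ± 0.53. The NF-kB and inflammation miRNAs were higher for 4 of 6 members with a median of 0.23 (adjusted p = 0.0321). Among the 4 members with a mean value of at least 100 the median was 0.04 (camera adjusted p = 0.755). Besides mir-146a and mir-147 above, mir-132 measured 8.47 ± 0.80 and 8.16 ± 0.97 and mir-21a 13.32 ± 0.57 and 13.41 ± 0.85. No member passed singly. Over all 18 lists, 1 passed without old 2, 2 without old 4, 2 without young 4 and 2 without both old 3 and young 4. The Sfmbt2 list missed the threshold without old 2 (median 0.52, adjusted p = 0.0501), and its median was 1.09 without young 4. Over all settings it was run in, the Sfmbt2 median ranged from 0.34 to 1.38. The fibroblast and smooth muscle list missed it without old 2 (adjusted p = 0.0501), without old 4 (median 0.13, adjusted p = 0.0600) and without young 4 (median 0.49, adjusted p = 0.0792). The inflammation list missed it without old 2, old 3, old 4, young 2 or young 4 (adjusted p from 0.0501 to 0.135), with a median of -0.068 without old 4, 0.15 without young 2 and 0.63 without young 4.

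**Figure D3:**
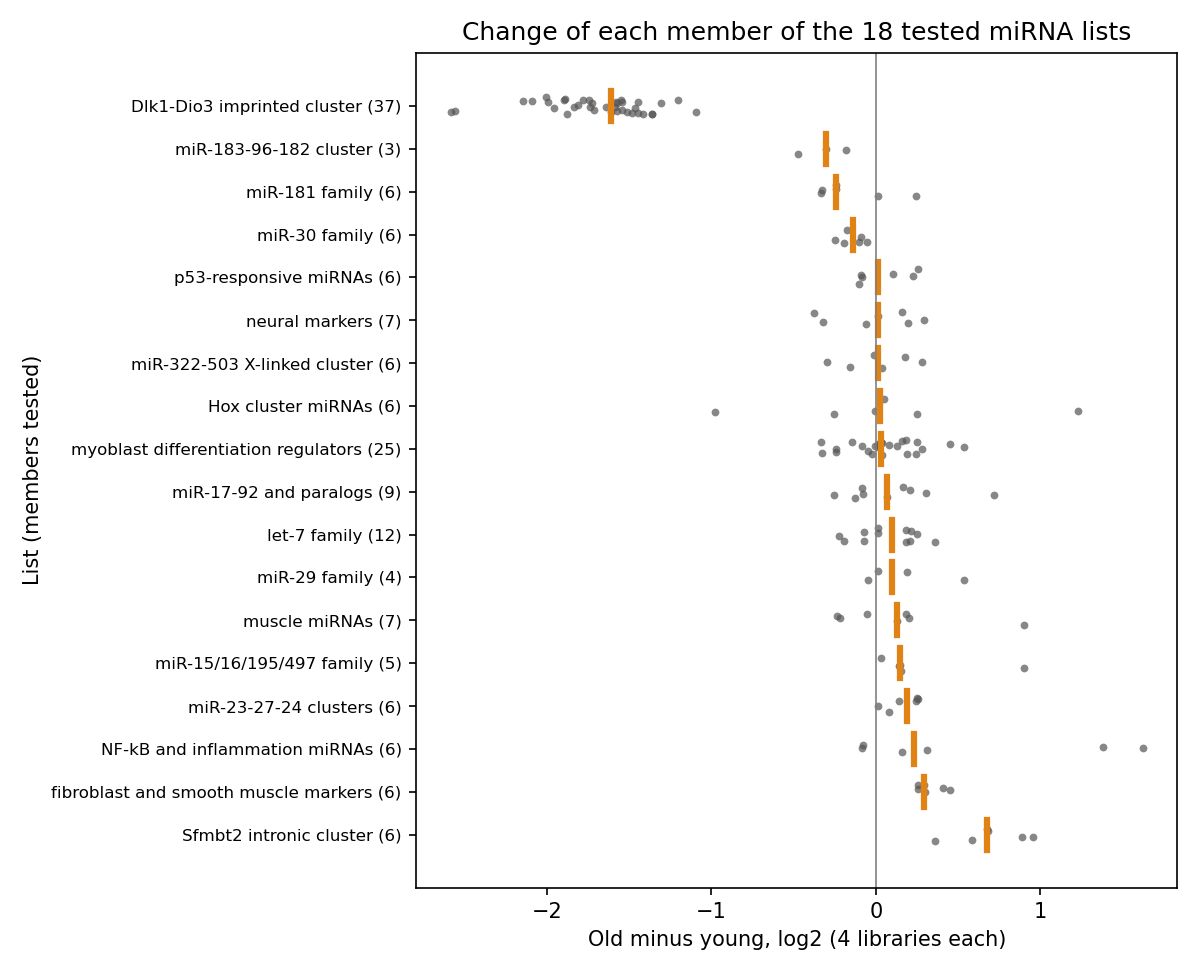
Log2 difference between old and young means for each compared member of the 18 tested lists, with 1 grey point per miRNA and an orange bar at the list's median; the number of members is in brackets. The 37 Dlk1-Dio3 miRNAs lie between -2.58 and -1.10, while the medians of the other lists lie between -0.30 and 0.68.

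The muscle and myoblast lists did not pass between old and young cells with all 8 libraries, and the sign of their medians changed with single libraries. Of 12 listed muscle precursors 7 were compared, and 4 of these 7 members were higher in old libraries, with a median of 0.13 (camera adjusted p = 0.637). The copies mir-133a-1 and mir-133a-2 ran parallel over the libraries, and mir-208b was at the floor of 0 in old 4 and young 4. Besides mir-486, mir-206, a muscle-specific miRNA of differentiating myoblasts, measured 15.90 ± 0.17 in old and 15.72 ± 0.72 in young libraries, and mir-133a-1 measured 13.34 ± 0.65 and 13.57 ± 1.25. Of 25 regulators of satellite cells and myoblast differentiation, 18 of which other lists also hold, 16 were higher and 9 lower, with a median of 0.03 (adjusted p = 0.519) that was -0.01 after TMM rescaling. In this list mir-181a-2 measured 18.07 ± 0.25 and 18.31 ± 0.51, and mir-378a measured 16.99 ± 0.34 and 17.14 ± 0.13. The X-linked cluster of mir-322 and mir-503, induced when myoblasts differentiate, was higher for 3 and lower for 3 members, with a median of 0.01 (adjusted p = 0.680), or -0.03 after TMM rescaling. Its members mir-351 and mir-503 measured 17.11 ± 0.54 and 9.02 ± 0.24 in old and 17.41 ± 1.35 and 8.74 ± 1.27 in young libraries. The muscle list passed camera without young 3, with all 7 members higher (median 0.30, adjusted p = 0.0119), but not with an estimated correlation (adjusted p = 0.912) nor by fry (adjusted p = 0.958). Its median was -0.36 without young 4, -0.34 with array weights, -0.054 with a pseudocount of 10 and -0.75, with all 7 members lower, without both old 3 and young 4 (adjusted p = 0.183). The median of the differentiation regulators was -0.16 without old 4, -0.073 without young 1 and -0.11 without young 3. That of the X-linked cluster was -0.16 without old 2, -0.043 without old 3, -0.091 without young 1, -0.43 without young 4 and -0.28 with array weights.

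Families linked to proliferation and differentiation did not pass with all 8 libraries either. miR-17-92 and its paralogs were higher for 5 of 9 members (median 0.06, camera adjusted p = 0.637), with mir-25 at 13.86 ± 0.60 in old and 13.94 ± 0.67 in young libraries. The let-7 family was higher for 8 of 12 members (median 0.10, adjusted p = 0.357), with let-7b at 15.59 ± 0.30 and 15.23 ± 0.55. The family of miR-15, miR-16, miR-195 and miR-497 was higher for 5 of 5 members (median 0.15, adjusted p = 0.336), with mir-15b at 11.74 ± 0.94 and 11.71 ± 0.79. The miR-23-27-24 clusters were higher for 6 of 6 members (median 0.19, adjusted p = 0.315), with mir-27b at 16.20 ± 0.52 and 16.18 ± 0.33 and mir-24-1 at 13.96 ± 0.46 and 13.71 ± 0.54. The miR-29 family, which targets collagen transcripts, was higher for 3 of 4 members (median 0.10, adjusted p = 0.519), with mir-29a at 12.65 ± 0.41 and 12.46 ± 0.75. The miR-30 family was lower for 6 of 6 members (median -0.14, adjusted p = 0.679), with mir-30d at 15.87 ± 0.40 and 16.12 ± 0.89. Its median was 0.03 after quantile normalization and 0.06 after rescaling to the sum without mir-486 and mir-3107. The miR-181 family was lower for 4 of 6 members (median -0.24, adjusted p = 0.637), with mir-181b-1 at 13.57 ± 0.25 and 13.90 ± 0.70. Its median was -0.029 without young 2, -0.13 without old 2 and -0.40 without young 1. The p53-responsive miRNAs were higher for 3 and lower for 3 (median 0.01, or -0.03 after TMM rescaling, adjusted p = 0.679), with mir-34c at 13.94 ± 0.67 and 14.03 ± 0.68. Of mir-221 and mir-222, too few for a list test, mir-221 measured 14.30 ± 0.66 in old and 14.31 ± 0.81 in young libraries, and mir-222 differed by -0.09 with an SE of 0.47. Calls were gained in 3 of these lists: the miR-15 and miR-16 family passed without old 1 (median 0.52, adjusted p = 0.0163), and let-7 (median 0.29, adjusted p = 0.0249) and the miR-23-27-24 clusters (median 0.39, adjusted p = 0.0216) passed after rescaling to the sum without mir-486 and mir-3107. With an estimated correlation in the same settings the adjusted p was 0.733 for the miR-15 and miR-16 family and 0.486 for each of the other 2, and with fry it was 0.936, 0.203 and 0.233. Without old 4 the medians turned negative for miR-17-92 (-0.17), let-7 (-0.042), the miR-15 and miR-16 family (-0.23), miR-23-27-24 (-0.057), miR-29 (-0.12) and the p53-responsive miRNAs (-0.18). Without young 1 they did so for miR-17-92 (-0.15), let-7 (-0.060), miR-29 (-0.020) and the p53-responsive miRNAs (-0.15), and without young 3 for miR-17-92 (-0.031), miR-29 (-0.12) and the p53-responsive miRNAs (-0.083). Without young 2 those of miR-17-92 (-0.036) and the p53-responsive miRNAs (-0.054) were negative. The miR-30 median was 0.18 without young 4 and 0.012 without old 1. Some precursor copies with the same mature miRNA ran parallel in this file, so that they in effect share reads and their separate levels cannot be read. The difference between let-7a-1 and let-7a-2 had an SD of 0.0083 over the 8 libraries. mir-181a-1 and mir-181a-2 were at 17.92 and 18.14 in old 1 and at 18.74 and 18.96 in young 2. The member counts of these and other lists hold such copies as separate members.

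The miRNAs of the Hox clusters and of the cluster of mir-183, mir-96 and mir-182 did not pass between the groups, and the sign of their medians changed with single libraries. The Hox list was higher for 3 and lower for 3 of its members (median 0.02, or -0.02 after TMM rescaling, camera adjusted p = 0.724), with mir-615 at 14.11 ± 0.15 in old and 13.86 ± 0.77 in young libraries and mir-196a-2 at 11.67 ± 0.34 and 11.67 ± 0.62. The mir-183 cluster was lower for 3 of 3 members (median -0.30, adjusted p = 0.679), with mir-183 at 15.12 ± 1.18 and 15.42 ± 1.40 and mir-182 at 14.91 ± 1.12 and 15.38 ± 1.47. Its median was 0.28 without old 2 and 0.27 without young 4, with all 3 members higher in both cases, and 0.070 with array weights. The Hox median was -0.14 without old 4, -0.20 without young 1 and -0.26 without young 3.

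Listed markers of blood, endothelial and pluripotent cells were low in these cultures. Those of fibroblasts and smooth muscle, given above, were abundant, and some neural markers were not low either. Of the listed blood cell miRNAs only mir-150 was abundant enough to compare, at 3.75 ± 0.58 in old and 3.03 ± 1.45 in young libraries. The endothelial mir-126a measured 3.64 ± 0.47 and 3.71 ± 0.99, and mir-126b 3.92 ± 0.52 and 4.03 ± 0.98. mir-126b lies inside mir-126a on the other strand, and both ordered the libraries alike (mir-126a from 2.96 in young 1 to 5.11 in young 4, mir-126b from 3.29 to 5.43). They may largely list the same reads, so they do not count as separate markers. Of the epithelial markers, mir-205 measured 5.93 ± 1.49 and 6.33 ± 0.75, and mir-203 measured 3.24 ± 0.42 and 3.72 ± 0.70. None of the 14 listed precursors of pluripotent cells was kept. The neural markers were higher for 4 of 7 members (median 0.01, or -0.03 after TMM rescaling, camera adjusted p = 0.983), while their mean difference was -0.02 and camera's direction was lower. mir-128-1, the most abundant of them, measured 10.27 ± 0.34 and 10.64 ± 0.09 (SD, n = 4 each). The list's median was -0.20 without old 3, -0.11 without old 4, -0.18 without young 1 and -0.051 without young 3.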

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

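Of the tests in this part, those of an exchange of labels, a shared batch and the scaling were chosen after the result was seen; the counts of other splits were chosen before. In groups of 4 libraries, 224 in all, the highest or lowest library was set apart by a gap that filled most of the group's range in 16, where chance gives about 11.2 (1 in 20). Of these, 6 concerned old 3, 5 old 4, 2 young 4, and 1 each old 2, young 2 and young 3. The flags overlap and are not separate events, so the comparison with chance is only rough. Those of old 3 were miR-431, mir-411, mir-541, the mean of their own list and both copies of mir-133a. Those of young 4 were mir-92a-1 and the mean of the list that holds it.

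Old 3 stood apart from the other old libraries in the Dlk1-Dio3 miRNAs. Its miR-431 was at 10.14 against a median of 6.17 in the other old libraries, mir-411 at 12.41 against 8.49, mir-541 at 14.89, and the mean of the 37 members at 8.99 against 4.86. Old 3 was also high in the muscle miRNAs mir-133a-1 (14.30 against 12.99) and mir-133a-2 (13.69 against 12.38).

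The pattern in the Dlk1-Dio3 cluster, with old 3 among the young libraries and young 4 among the old ones, was weighed against 3 technical explanations. Scaling by a total that mir-486 and mir-3107 dominate is argued against, since old 3 still stood 4.07 above the other old libraries after TMM rescaling. An exchange of the labels of old 3 and young 4 stays open. Of 321 miRNAs outside the cluster, 41 (12.8%, against 10% by chance) separated the other libraries by group, against 8 to 37 for the other 15 pairs. Young 4 left out with old 1, old 2 or old 4 gave 37, 31 and 24. Old 3 left out with young 1, young 2 or young 3 gave 14, 11 and 12, and old 4 with young 3 gave 26. The count thus went more with young 4 than with this pair. Of the 41, 53.7% placed both libraries with the opposite group and 2.44% both with their own. But old 4 and young 3 gave 57.7% and 11.5%, old 3 and young 2 gave 27.3% and 0%, and the median of the other pairs for the opposite group was 23.1%. This pair was therefore extreme in neither share. A batch shared by libraries of the same number could not be decided either (mean correlation outside the cluster 0.26, the second highest of 24 matchings, exact p = 0.0833; over all 359 miRNAs, which include those of the pattern itself, 0.40, the highest of 24, exact p = 0.0417). Differences between animals or cultures in the activity of this imprinted locus, with or without a part of age, were not tested and remain open.

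Since the real split gave 0 passing miRNAs, all 35 splits of the 8 libraries into 4 and 4 gave at least as many by construction (highest other 48), and this count says nothing about chance. Of the 35 splits, 26 gave at least the real split's 4 at an unadjusted p under 0.05 (highest other 94), 15 at least its 4 lists by camera (highest other 8), and 8 at least its difference of 1.69 in the cluster mean (highest other 3.42), so that chance could not be excluded for any of these 3 results. The split of old 1, old 2, old 4 and young 4 against the rest gave 48 passing miRNAs, 37 of them on the cluster's list, while no other gave more than 3. That split is the grouping of the libraries already seen in the cluster, so its count restates this structure of the samples and is no separate evidence on the labels.

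Other libraries set apart were as follows, each with the median of the other 3 in its group. Old 4 was high in mir-126a (4.34 against 3.43), mir-196b (12.32 against 11.19), mir-29a (13.26 against 12.47) and the miR-181 family mean (14.88 against 14.48), and low in mir-351 (16.31 against 17.43). Young 4 was high in mir-92a-1 (19.75 against 18.63) and in the mean of miR-17-92 and paralogs (11.98 against 10.41). Old 2 was low in mir-183 (13.36 against 15.68). Young 2 was high in mir-27b (16.67 against 16.01), and young 3 was high in mir-6997 (4.46 against 3.62).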

How the results depend on the processing

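Of 23 alternatives, 5 were added after seeing the data. In 22 of them 0 miRNAs passed, with 0 to 39 at an unadjusted p under 0.05; without both old 3 and young 4, libraries chosen on the outcome, 33 passed and miR-431 was at -3.67 (adjusted p = 0.00720), with mir-380 at -4.59 and mir-668 at -3.46 also past the threshold. Elsewhere miR-431 stayed between -2.81 and -1.10, with an adjusted p of at least 0.188, and every kept Dlk1-Dio3 member was lower in old libraries in all 23. Leaving out 1 library gave 0 passing miRNAs each time, miR-431 from -2.81 to -1.10, and 1 to 5 lists past camera; 32 of the 37 Dlk1-Dio3 members passed adjusted over the list alone without old 3, and 0 without any other single library. From 4 lists, the count moved to 2 with no filter, with a mean of at least 100 or without both old 3 and young 4, and to 0 with an estimated correlation or fry. The change with a filter comes with other members being tested; for the rest the cause was not tested. The Dlk1-Dio3 median was -1.61 in these 2 list tests, with adjusted p of 0.630, given the members' correlation of 0.897, and of 0.992; with other settings the adjusted p with an estimated correlation ranged from 0.143 to 0.998. This list passed camera in all 24 settings, Sfmbt2 in 22 of the 23 it was run in (too few members had a mean of at least 100), fibroblast and smooth muscle in 18 of 24 and inflammation miRNAs in 10 of 24. Leaving out 1 library, the inflammation median ranged from -0.068 without old 4, where it reversed (the cause was not tested), to 0.63 without young 4, and it was 0.64 without both old 3 and young 4. Of the 18 lists, 14 turned the sign of their median when some single library was left out, and 4 that had not passed gained a call in 1 setting each. The share of mir-3107 differed by -1.01 to 6.91 points and that of the 10 most abundant by -1.15 to 3.82 points when 1 library was left out, both reversed only without young 4, the library with the lowest share. Within-group minus between-group correlation was -0.00210 by Spearman and -0.00202 by Pearson. Rescaling to the sum without mir-486 and mir-3107 shifted the median of all miRNAs from -0.05 to 0.14. With quantile normalization mir-378a went from -0.14 to 0.40.

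The labels give libraries of the same number nothing else in common, and the numbers were not taken as pairing them. Their deviations correlated by -0.06, 0.43, 0.66 and 0.58 for numbers 1 to 4 over all 359 miRNAs, where 6 of 8 libraries correlated best with their own number. Outside the span of the Dlk1-Dio3 cluster they correlated by 0.14, 0.38, 0.15 and 0.38, where 4 of 8 did. This is a hint from the data and not the design. With the replicate number as a block, 0 miRNAs passed in limma, 39 had an unadjusted p under 0.05, 3 lists passed camera, the inflammation list no longer did (adjusted p = 0.0683), and the Dlk1-Dio3 median was -1.61, with 28 of its 37 members passing adjusted over the list alone. Under the block miR-431 was at -1.81 and lower in the old library of all 4 pairs (limma p = 0.00523, adjusted p = 0.188; exact two-sided sign-flip permutation p = 0.125, the smallest that 4 pairs can give). The cluster mean of the old library lay below that of the young one in all 4 same-number pairs (-3.52, -1.95, -0.57 and -0.73), as in 6 of the 24 ways to match the libraries. Count-model tests on reads, planned in case the file held counts, were not run. The floor at 0 and the few reads of low precursors limit what can be seen there.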

Other observations

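Both tests of miR-10b below were run once its spread had been seen, the one on shared reads being chosen after the result, as was the test along the Dlk1-Dio3 cluster.

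miR-10b, encoded in introns of Hoxd3 and Hoxd4 on chromosome 2 (74726070 to 74726137, mm10), varied most of the 359 miRNAs between libraries of a group. It was at 8.32, 10.93, 10.27 and 14.21 in old 1 to old 4 and at 4.78, 7.29, 12.82 and 13.92 in young 1 to young 4, a range of 59.3-fold in old and 564-fold in young libraries. Counting noise is argued against, since the library with the fewest held 56.1 recovered reads. Reads shared with the near-identical miR-10a are argued against too: the difference between them had an SD of 4.14 over the 8 libraries, against 0.0083 for let-7a-1 and let-7a-2, which share a mature sequence. No biological explanation was tested.

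miR-10a, on chromosome 11, was at 4.58, 5.70, 9.88 and 5.90 in old and 5.75, 10.44, 7.44 and 6.35 in young libraries, and did not follow miR-10b.

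The Dlk1-Dio3 miRNAs moved as a block. A single axis held 90.0% of the variance of the 37 members over the 8 libraries, against a median of 43.7% and a highest value of 65.5% in 1000 random sets of 37 miRNAs outside the cluster. Moving together was not particular to this cluster. The members' correlation estimated by camera was 0.897 here, 0.975 for the mir-183 cluster and 0.874 for the miR-30 family. Other tested lists were lower, down to 0.166 for the neural markers. The hypothesis that the part up to miR-370 and the part from miR-379 on differ in their change between old and young was not borne out by the medians. These were -1.61 for 13 and -1.66 for 24 precursors (difference 0.05, permutation p = 0.712). The permutation treated precursors that move together as separate, so its p does not measure the variation between animals.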
